A study of Mus musculus with 4 samples.

How the data were processed

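RNA sequencing was carried out on testicular interstitial cells of C57BL/6J mice that carried mFLE-Cre and the CAG-CAT-EGFP reporter, in which EGFP is switched on where Cre recombinase has acted. Per the labels, testes were dispersed at postnatal day 10 and EGFP-expressing cells were sorted by laminin staining into a laminin-negative and a laminin-positive population, with 2 samples of each. Total RNA was extracted with the RNeasy micro kit, and libraries were made with the NEBNext Ultra Directional kit, per the labels' protocols. Each sample label calls its cells EGFP-positive, while the design text of the series describes the laminin-negative cells as weak in EGFP. Nothing in the labels says that the samples of a population came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

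The deposited values are FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) for each library, per the file headers, in a table of 22802 gene loci. The submitters' processing notes name TopHat2 2.1.1 and Cufflinks 2.2.1, without their roles. The genome build, annotation, strand setting and any scaling between libraries are not given in the sources used here. Loci of 18008 rows with a unique symbol were compared with GENCODE M21 genes of the same symbol on GRCm38, and 99.7% overlapped. GRCm38 coordinates from that annotation are therefore given for named genes. The table lists 4547 rows at 0 in every library, 207 rows that name several genes and 367 rows that share a symbol with another row. Gene symbols had been turned into calendar dates in 26 rows, and these rows were kept under their locus identifiers. A value was at 0 in one library and above 10 FPKM in another in 4 rows.

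FPKM values hold no read counts, and the number of sequenced fragments is not given in the sources used here. A depth was sought in the lowest values of genes with 1 annotated transcript, as the median within a preset window. It put 1 FPKM of a 2 kb transcript at 51.3 to 55.1 fragments across the libraries. A step of a single fragment would leave the band just below the window nearly empty. That band held 22 to 49 genes, against 137 to 183 in the wider window, so no step was seen and the depth stays unknown. Counting error adds to the spread between replicates, most of all for genes of a few FPKM or less. With the estimate above, the chi-square per gene had a mean of 13.7 and a median of 3.25 between the laminin-negative libraries. Between the laminin-positive libraries these were 14.5 and 3.88. The chi-square scales with that estimate and takes in differences in depth, so it cannot show spread beyond counting noise. Replicates shared an identical value above 0 in 0 rows for laminin-negative and 1 row for laminin-positive libraries. None was therefore treated as the same values listed again, but separate preparations of the same cells would also differ in this way.

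Genes with an FPKM of at least 1 in at least 2 libraries were tested, which left 12348. Values were transformed to log2(FPKM + 1), which understates the change of genes near or below 1 FPKM. Laminin-positive was compared with laminin-negative using limma 3.58.1 (R 4.3.3) with empirical Bayes moderation and an intensity trend, two-sided, without a replicate block. The p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The moderated test draws on 2 residual degrees of freedom and a median of 8.21 prior degrees of freedom borrowed across genes. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so none was used for single genes. Fold differences in the text are ratios of group mean FPKM, and log2 differences and their SE are on the log2(FPKM + 1) scale.

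Gene lists were written before the data were examined, as were the tests, the rule for named genes and the main set of alternatives. There were 21 lists with 250 genes, of which 249 were found in the table, 1 by an older symbol and 6 in rows that name several genes. The lists cover steroidogenesis, fetal Leydig cell, adult Leydig cell maturation, Leydig stem and progenitor, Hedgehog pathway, Notch pathway, smooth muscle and peritubular myoid, pericyte, laminin chains, other basement membrane, laminin receptors, interstitial matrix, cholesterol synthesis and uptake, respiratory chain, cell cycle, and immediate early and dissociation stress genes. Markers of Sertoli, germ, endothelial, macrophage and erythroid cells were included for other cell types that the sort could hold. The smooth muscle and pericyte lists also mark cell types that the sort could hold. Each list was tested against all other genes with camera in limma, two-sided, at a preset inter-gene correlation of 0.01 and adjusted over the lists. Camera was also run with the correlation estimated from the data, which leaves only the 2 residual degrees of freedom. Gene calls are given over all genes and adjusted over the list alone. A further 6 lists were chosen after the data were seen and are described only in the closing section.

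Named genes followed a rule of 3 parts. It took the 8 genes with the largest positive and the 8 with the largest negative log2 difference among genes that passed the threshold, did not overlap between groups and had a mean of at least 5 FPKM in the higher group. It also took the member of each list with the largest rise, the largest fall and the highest mean, and a set of Leydig, interstitial and laminin genes fixed in advance. This gave 70 genes, of which 69 were tested. List members named because a count held 5 or fewer, and the genes named in the closing section, were chosen after their values were seen, and 1 list member is not reported here by name. In the annotation, 17 of the named genes share exon sequence with another gene, and 7 of them with a protein-coding gene. These were Tagln with Pcsk7, Gli1 with Arhgap9, Nid2 with Rtraf, Cox6c with Vps13b and Col4a1 with Col4a2 on opposite strands, and Itga1 and Fdps with an unnamed gene on the same strand. Their values are uncertain to that extent. Reads may likewise have been split among the near-identical Hsd3b genes and among the actin genes.

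On data simulated from the 12348 tested genes with 200 genes changed, limma recovered 28.4% of genes changed by 0.5 on the log2 scale, 73.1% of those changed by 1 and 100% of those changed by 2. The changed genes were drawn only from genes above a set level in laminin-negative cells. Recovery of genes at lower levels was not tested. False calls made up 2.90% of all calls. In the data 52.9% of genes were called, far more than were changed here, so recovery there may differ. The simulated noise came from the replicate spread alone, so these values do not cover effects of animals or sorts. Alternatives covered the pseudocount, the filter, the scaling of libraries, the variance model, the replicate block, each replicate left out in turn and, after the data were seen, a size threshold, equal FPKM sums without the ribosomal RNA gene Rn45s, the removal of length and GC trends, and only unshared loci. Their effects are given in the closing section, together with the correlation of replicate differences between the populations. Summaries and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Erythroid markers passed the filter in no case and were not tested, and no library was left out of the main comparison.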

Results

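EGFP-expressing interstitial cells of the mouse testis at postnatal day 10 were profiled by RNA sequencing in 2 laminin-negative and 2 laminin-positive samples. FPKM summed to between 491475 and 548986 per library, and 11794 to 12011 loci reached 1 FPKM. Read totals were not given, and the depth could not be read from the lowest values. Across the 12348 tested genes, log2(FPKM + 1) correlated at r = 0.994 between the laminin-negative and r = 0.996 between the laminin-positive libraries, against 0.898 to 0.903 between populations. Genes are not independent replicates, so these values describe similarity only. Principal component 1 held 95.05% of the variance and separated the populations.

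The comparison asked how EGFP-expressing interstitial cells that stain for laminin differ from those that do not. Since the design text calls the laminin-negative cells weak in EGFP, the populations may differ in EGFP level as well as in laminin staining. All 12 genes of a smooth muscle and peritubular myoid list were higher in laminin-positive cells, and 13 of 14 tested steroidogenesis genes were lower. As lists, they lost their calls in camera with an estimated correlation (adjusted p = 0.242 and 0.252). That run rests on 2 residual degrees of freedom and called 0 of the 20 tested lists, so it cannot tell weak lists from strong ones. Smooth muscle actin Acta2 averaged 3603 ± 7.71 FPKM (SD, n = 2) in laminin-positive and 94.5 ± 4.16 in laminin-negative cells, a 38.1-fold difference. Cyp17a1, the enzyme that makes androgen precursors, averaged 268 ± 12 FPKM in laminin-negative and 9.13 ± 0.977 in laminin-positive cells (29.4-fold). The laminin-negative cells also held more of the row that merges the Leydig cell hormone gene Insl3 with its neighbour Jak3, at 3951 ± 182 against 107 ± 27.9 FPKM (37.0-fold). Tcf21, a transcription factor of interstitial cells, was abundant in both populations, at 335 ± 8.03 FPKM in laminin-negative and 471 ± 1.60 in laminin-positive cells.

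By limma, 3288 of the 12348 tested genes were higher and 3245 lower in laminin-positive cells, 52.9% of all tested. A log2 difference of at least 1 was reached by 900 of the higher and 727 of the lower genes, and of at least 3 by 77 and 70. Both libraries of one population lay above both of the other for 9531 genes (77.2%, where chance gives 33.3%). The median log2 difference over all tested genes was 0.01. With libraries set to equal FPKM sums after leaving out Rn45s the median became 0.12 and the split 4275 higher to 2371 lower (64.3% higher against 50.3%), so directions of small differences depend on the scaling. Without variance shared across genes, 1346 were higher and 1211 lower.

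**Figure D1:**
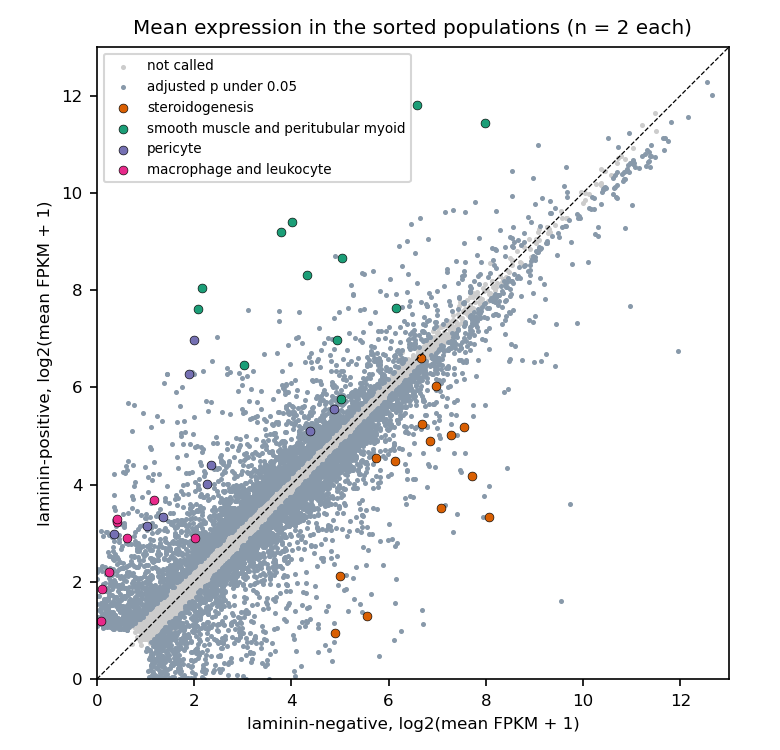
Each point is a tested gene, with log2 of the mean FPKM + 1 in laminin-negative cells on the horizontal and in laminin-positive cells on the vertical axis (2 libraries each), and 4 gene lists are coloured. All 12 smooth muscle genes lie above the dashed line of equality and 13 of the 14 tested steroidogenesis genes are called below it.

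Among the 8 largest rises, the smooth muscle genes were Actg2 (chromosome 6, 83512905 to 83536265, GRCm38), Cnn1 (chromosome 9, 22099216 to 22109630), Tagln (chromosome 9, 45929619 to 45936058), Myh11 (chromosome 16, 14194535 to 14291372) and Acta2 (chromosome 19, 34241090 to 34255590). Actg2 rose from 3.49 ± 0.134 to 263 ± 6.70 FPKM, a log2 difference of 5.88 (SE 0.08, limma adjusted p = 2.00e-11). The calponin gene Cnn1 stood at 3.23 ± 0.125 in laminin-negative and 195 ± 0.936 FPKM in laminin-positive cells. Myosin heavy chain Myh11 differed 44.6-fold and transgelin (Tagln) 45.7-fold. The other 3 were the cell adhesion gene Mcam (41.6-fold), the protein kinase C gene Prkcb (70.4-fold) and Fam229a (90.1-fold). Prkcb and Fam229a averaged 0.689 and 0.557 FPKM in laminin-negative cells, so the size of their ratios is uncertain.

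The largest fall was that of Clec3b, which encodes tetranectin (chromosome 9, 123150946 to 123157432), from 746 ± 20.3 FPKM in laminin-negative to 2.02 ± 0.853 in laminin-positive cells (368-fold, log2 difference −7.98, SE 0.15, limma adjusted p = 5.78e-11). Dlk1, an imprinted regulator of progenitor cells (chromosome 12, 109452823 to 109463336), fell from 847 ± 19.0 to 11.1 ± 2.45 FPKM. Among the 8 largest falls, dermatopontin (Dpt) was 86.2-fold, lumican (Lum) 139-fold and the microfibril gene Mfap5 61.7-fold lower in laminin-positive cells. The aldehyde dehydrogenase gene Aldh3a1 was 92.0-fold and S100b 75.9-fold lower, and the merged Insl3 and Jak3 row completed the set at a log2 difference of −5.22 (SE 0.14, limma adjusted p = 5.19e-10). In laminin-positive cells Lum, Aldh3a1 and S100b averaged 0.392, 0.743 and 0.998 FPKM, so the size of their ratios is uncertain.

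Of 14 tested steroidogenesis genes, 13 fell in laminin-positive cells, over all genes as well as adjusted over the list alone. The list had a median log2 difference of −2.32 (camera adjusted p = 2.60e-11). That call was lost at adjusted p = 0.252 with an estimated correlation. Cyp11a1, which cleaves the cholesterol side chain (chromosome 9, 58006411 to 58027023), fell from 133 ± 0.354 to 10.4 ± 1.27 FPKM. Hsd3b1 fell from 209.7 ± 2.97 to 17.1 ± 1.25 FPKM and the cholesterol transporter Star from 31.0 ± 0.763 to 3.35 ± 0.302 FPKM. Nr5a1, the transcription factor that drives steroidogenic genes (chromosome 2, 38692656 to 38714542), fell less, from 102 ± 8.61 to 36.9 ± 0.820 FPKM (log2 difference −1.44, SE 0.08, limma adjusted p = 9.67e-08). Gata4 was the tested member that did not pass, at 101 ± 1.97 and 96.0 ± 1.83 FPKM (limma adjusted p = 0.431). Hsd17b3, the testosterone-forming enzyme of adult Leydig cells, was below the filter at 0.397 ± 0.170 and 0.526 ± 0.159 FPKM. Markers of macrophages, Sertoli cells and germ cells moved the other way, with median log2 differences of 2.12, 1.32 and 0.92 (adjusted p = 0.242 for each with an estimated correlation).

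Fetal Leydig markers fell in 5 of 6 tested rows, namely Insl3 with Jak3, Ren1 with Ren2, Dlk1, Crhr1 and Thbs2 (median log2 difference −2.87, camera adjusted p = 9.25e-04). This became adjusted p = 0.242 with an estimated correlation. Adjusted over the list alone, 5 were lower and 1, Agtr1a, was higher, as it also was without an intensity trend, with equal FPKM sums or with length and GC trends removed. Thbs2 differed little, at 60.9 ± 1.93 and 50.04 ± 0.505 FPKM (log2 difference −0.28, SE 0.07, limma adjusted p = 0.00739), and its call was lost without laminin-positive replicate 1 (0.0529), without variance shared across genes (0.0581) and with equal FPKM sums, in a range of 5.68e-04 to 0.116 over the alternatives. Adult Leydig maturation genes fell in 6 of 7 tested cases of 10 listed, also when adjusted over the list alone (median log2 difference −2.35, camera adjusted p = 8.79e-05, and adjusted p = 0.242 with an estimated correlation). The others were below the filter, namely Hsd17b3, Hpgds (0.0374 and 0.276 FPKM) and Sult1e1 (0 FPKM in every library). This list shares Hsd3b6 and Hsd17b3 with the steroidogenesis list, so the lists are not independent. Vcam1, a cell adhesion gene, fell from 268 ± 17.5 to 14.7 ± 0.623 FPKM, whereas the prostaglandin D synthase gene Ptgds was higher in laminin-positive cells at 1.23 ± 0.102 against 0.470 ± 0.111 FPKM, a call lost without variance shared across genes.

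All 20 genes of cholesterol synthesis and uptake were lower in laminin-positive cells, over all genes and adjusted over the list alone (median log2 difference −0.91, camera adjusted p = 7.06e-10). The list had adjusted p = 0.242 with an estimated correlation. Dhcr7, the last enzyme of the pathway in its Kandutsch-Russell branch, fell from 50.1 ± 1.02 to 10.4 ± 1.5 FPKM. The farnesyl diphosphate synthase gene Fdps fell from 125 ± 7.26 to 43.5 ± 1.04 FPKM. With equal FPKM sums 19 of the 20 were called lower, and without variance shared across genes 11.

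**Figure D2:**
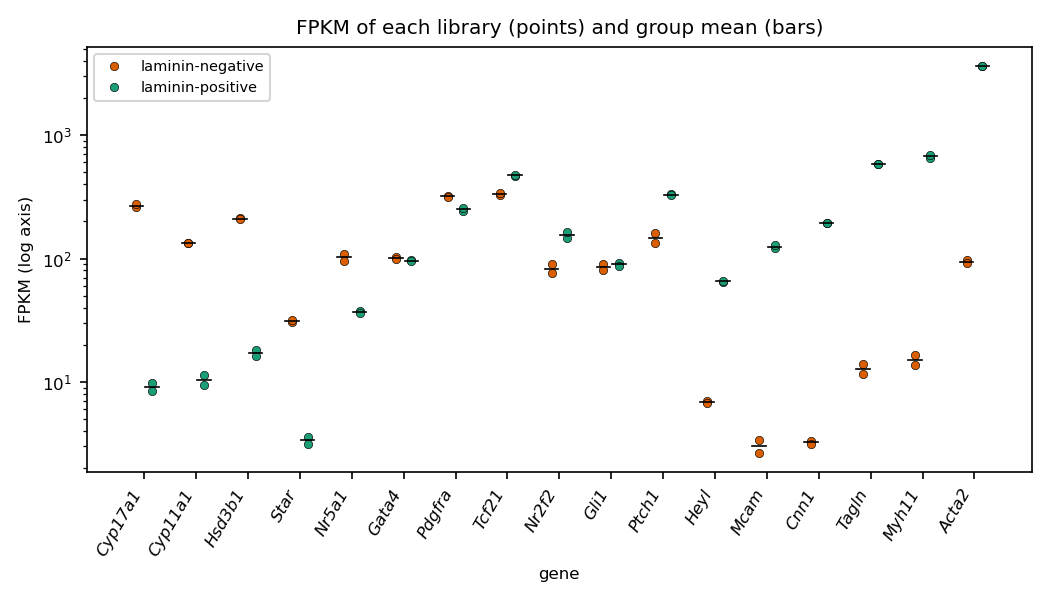
FPKM of named genes on a log axis, with a point for each of the 2 libraries of a population and a bar for the mean. Steroidogenic genes sit higher in laminin-negative libraries (Cyp17a1 at 268 against 9.13 FPKM), contractile genes higher in laminin-positive libraries (Acta2 at 3603 against 94.5 FPKM), and Gata4 and Gli1 lie close together.

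Every one of the 12 smooth muscle and peritubular myoid genes was higher in laminin-positive cells, over all genes and adjusted over the list alone (median log2 difference 3.80, camera adjusted p = 1.92e-12). The call did not hold at adjusted p = 0.242 with an estimated correlation. Pericyte markers were higher in 9 of 9 cases, likewise adjusted over the list alone (median log2 difference 2.04, camera adjusted p = 2.91e-07, and adjusted p = 0.242 with an estimated correlation). Mcam (chromosome 9, 44134469 to 44142727) rose from 3.01 ± 0.496 to 125 ± 5.40 FPKM. Whether the laminin-positive sort held smooth muscle cells, peritubular myoid cells or pericytes was not tested. In the same libraries macrophage markers were higher by a median log2 difference of 2.12, Sertoli cell markers by 1.32 and germ cell markers by 0.92, each at adjusted p = 0.242 with an estimated correlation.

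Notch pathway genes were higher in laminin-positive cells in 8 of 11 cases and lower in 1, Notch1, and 9 and 1 when adjusted over the list alone (median log2 difference 0.55, camera adjusted p = 0.00131). The list had adjusted p = 0.286 with an estimated correlation. When no variance was shared across genes, limma called 5 higher and 0 lower (8 and 0 at an unadjusted p under 0.05), and the calls of Notch1 and Hes1 were lost. The Notch target Heyl (chromosome 4, 123233556 to 123249875) rose from 6.86 ± 0.197 to 65.3 ± 1.25 FPKM, while Notch1 fell from 4.87 ± 0.729 to 3.17 ± 0.0469 FPKM. Hes1, another target, differed little at 48.7 ± 3.62 and 58.8 ± 0.177 FPKM (limma adjusted p = 0.0137), and its call was lost without laminin-negative replicate 1 (0.0615), laminin-positive replicate 1 (0.0622) or laminin-positive replicate 2 (0.0577), in a range of 0.00109 to 0.144 over the alternatives.

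Leydig stem and progenitor markers went both ways, with 5 of 15 higher (Pdgfrb, Nr2f2, Tcf21, Itgav and Wt1) and 8 lower in laminin-positive cells, the same numbers adjusted over the list alone (median log2 difference −0.19, camera adjusted p = 0.425). Of the 15, 3 were called higher and 3 lower without variance shared across genes, which ended the calls of Nr2f2, Wt1 and Pdgfra. Nr2f2, a nuclear receptor of interstitial progenitors, rose from 82.7 ± 9.54 to 156 ± 12.2 FPKM, and Wt1 from 1.08 ± 0.0380 to 4.11 ± 0.880 FPKM. The growth factor receptor gene Pdgfra fell slightly, from 319.6 ± 4.04 to 251 ± 9.85 FPKM (log2 difference −0.35, SE 0.07, limma adjusted p = 0.00199). Ly6a, the gene of the Sca-1 surface antigen, fell from 15.6 ± 1.42 to 0.117 ± 0.103 FPKM, and the intermediate filament gene Vim from 1212 ± 52.4 to 569.6 ± 15.7 FPKM. Neither Nr2f1 nor Nes passed the test, at limma adjusted p = 0.835 and 0.899.

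Hedgehog pathway genes were also split, with 4 of 10 higher (Ptch1, Hhip, Gli2 and Gli3) and 3 lower, among them Cdon and Gas1, equally so adjusted over the list alone (median log2 difference 0.08, camera adjusted p = 0.958). Of the 10, 2 were called higher and 3 lower without variance shared across genes, and Ptch1 lost its call. Ptch1, the Hedgehog receptor and a target of the pathway, rose from 147 ± 19.4 to 329 ± 2.96 FPKM, and the inhibitor Hhip from 14.2 ± 1.15 to 58.9 ± 5.97 FPKM. The coreceptor gene Cdon fell from 42.7 ± 3.93 to 9.44 ± 0.0483 FPKM. Gli1, a transcription factor of the pathway (chromosome 10, 127329882 to 127341974), was at 85.7 ± 7.25 and 89.5 ± 2.67 FPKM (log2 difference 0.06, SE 0.08, limma adjusted p = 0.518). Smo and Boc did not pass the test either.

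Among 8 tested laminin chains, 4 were higher in laminin-positive cells (Lama2, Lama5, Lamb2 and Lamc3) and 2 lower (Lama1 and Lama4), or 5 and 2 adjusted over the list alone and 5 and 1, without Lama1, when no variance was shared across genes (median log2 difference 0.42, camera adjusted p = 0.136). Lamc3, the most abundant chain in laminin-positive cells, rose from 370.0 ± 10.4 to 1399 ± 35.5 FPKM (chromosome 2, 31887291 to 31946539), and Lama5 from 0.708 ± 0.0647 to 14.6 ± 1.13 FPKM. Lama1 fell from 20.1 ± 1.29 to 14.4 ± 0.223 FPKM, and Lama4 from 25.6 ± 0.556 to 10.97 ± 1.06 FPKM. Lamc1, the gamma chain of most laminins, was at 127 ± 4.26 and 119.8 ± 3.93 FPKM and Lamb1 at 429.7 ± 1.66 and 488 ± 4.59 FPKM, and neither passed the test (limma adjusted p = 0.361 and 0.0537).

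Laminin receptor genes were higher in laminin-positive cells in 6 of 7 tested cases, also adjusted over the list alone (median log2 difference 3.23, camera adjusted p = 2.56e-05, and adjusted p = 0.242 with an estimated correlation). Dag1 was the member that did not pass (limma adjusted p = 0.147), and 4 of the 7 were called higher without variance shared across genes. Itga1, an integrin subunit that binds collagen and laminin, rose from 1.17 ± 0.222 to 35.5 ± 1.15 FPKM, and its partner Itgb1 from 185 ± 3.8 to 315 ± 24.9 FPKM, a call that the same alternative ended (adjusted p = 0.0530). Other basement membrane genes were higher in 8 of 12 and lower in 4 cases (Nid1, Nid2, Col15a1 and Col18a1), likewise adjusted over the list alone (median log2 difference 0.57, camera adjusted p = 0.0491, and adjusted p = 0.601 with an estimated correlation). This list lay at the threshold, since its adjusted p was 0.0546 without laminin-negative replicate 2 and 0.0529 with the replicate block, in a range of 0.0173 to 0.0825 over the alternatives with the preset correlation. Col4a3, a collagen IV chain, rose from 28.6 ± 1.73 to 416 ± 23.1 FPKM and Col4a1 from 372 ± 21.2 to 976 ± 0.863 FPKM, while nidogen-2 (Nid2) fell from 145 ± 6.59 to 54.1 ± 0.142 FPKM.

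Interstitial matrix genes were lower in laminin-positive cells in 11 of 18 cases and higher in 3 (Eln, Bgn and Col6a1), the same adjusted over the list alone (median log2 difference −0.47, camera adjusted p = 0.00887). This list had adjusted p = 0.286 with an estimated correlation, and 0.129 under quantile normalization, in a range of 0.00314 to 0.129 over the alternatives with the preset correlation. Under quantile normalization 6 were higher and 9 lower, with equal FPKM sums 5 and 10, and without variance shared across genes 1 and 8. Only 2 were called higher without laminin-positive replicate 1, without laminin-positive replicate 2 and with libraries scaled by a trimmed mean of log ratios. Elastin (Eln, chromosome 5, 134702593 to 134747323) rose from 251 ± 49.1 to 2757 ± 38.7 FPKM, against the direction of most members. Lum fell from 54.5 ± 6.62 to 0.392 ± 0.170 FPKM. The collagen I gene Col1a2 fell from 2705 ± 139.5 to 2017 ± 56.6 FPKM (log2 difference −0.42, SE 0.09, limma adjusted p = 0.00258), a call lost without laminin-positive replicate 2 (0.0727), without variance shared across genes (0.0689) and under quantile normalization (0.579), in a range from 0.00156 to 0.579.

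**Figure D3:**
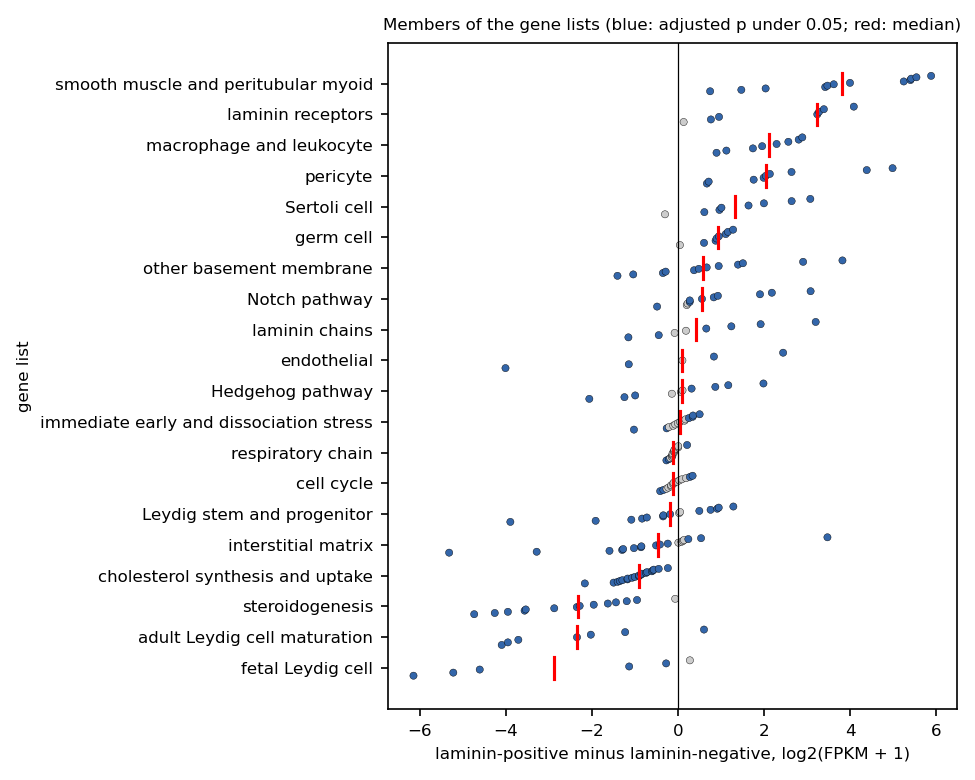
Log2 difference of each tested list member on the horizontal axis, with the 20 tested lists ordered by their median (red bars) and members with adjusted p under 0.05 in blue. Medians run from −2.87 for fetal Leydig cell to 3.80 for smooth muscle and peritubular myoid genes.

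Respiratory chain genes differed little, with 1 of 14 higher (Cox6c) and 2 lower (Sdha and Uqcrc1), or 0 and 1 adjusted over the list alone (median log2 difference −0.11, camera adjusted p = 0.267). Cox6c was at 550.0 ± 27.3 and 635 ± 7.13 FPKM and Sdha at 82.8 ± 0.961 and 68.4 ± 1.95 FPKM. Cell cycle genes showed 2 higher (Bub1 and Ccna2) and 2 lower (Mcm3 and Mcm6) of 14, or 0 and 2 adjusted over the list alone (median log2 difference −0.11, camera adjusted p = 0.527). Mcm6, a part of the replicative helicase, fell from 26.0 ± 0.424 to 19.2 ± 0.0541 FPKM, and Pcna was at 103 ± 9.28 and 95.03 ± 3.70 FPKM (limma adjusted p = 0.262). The calls of Bub1 and Cox6c were each lost without laminin-negative replicate 1 (limma adjusted p = 0.0846 and 0.0978), laminin-positive replicate 1 (0.0752 and 0.238) or laminin-positive replicate 2 (0.196 and 0.188). Over the alternatives they ranged from 0.0116 to 0.196 for Bub1 and from 0.00122 to 0.238 for Cox6c. When any of these 3 libraries was left out, 0 cell cycle genes were called higher by limma (2, 2 and 0 at an unadjusted p under 0.05), and 2, 3 and 1 were called lower. Without laminin-negative replicate 2, 3 were called lower. The Sdha call was lost without laminin-positive replicate 1 (0.0768), without variance shared across genes (0.0552) and with equal FPKM sums (0.119), in a range of 0.00460 to 0.119. With laminin-negative replicate 2, laminin-positive replicate 1 or laminin-positive replicate 2 left out, 1 respiratory chain gene was called lower, as under quantile normalization and with length and GC trends removed, and with equal FPKM sums limma called 0 lower (also 0 at an unadjusted p under 0.05). With trimmed mean scaling limma called 0 higher and 3 lower (0 and 5 at an unadjusted p under 0.05). Cell cycle calls were 3 higher and 1 lower with equal FPKM sums, 1 and 3 under quantile normalization, 2 and 4 with libraries scaled by a trimmed mean of log ratios and 3 and 4 with length and GC trends removed. Without variance shared across genes limma called 0 cell cycle genes higher and 3 lower (2 and 3 at an unadjusted p under 0.05) and 0 respiratory chain genes higher and 1 lower (0 and 2).

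Immediate early and stress genes, which dissociation of tissue can induce, were high in both populations. Of 13, 4 were higher (Nr4a1, Fosb, Jun and Dusp1) and 2 lower (Dnajb1 and Hspa1b), equally adjusted over the list alone (median log2 difference 0.04, camera adjusted p = 0.823). Fos was at 2872 ± 74.97 and 3185 ± 34.2 FPKM (limma adjusted p = 0.191, but 0.00118 under quantile normalization and 0.00490 with equal FPKM sums, in a range up to 0.567). Nr4a1 rose from 640.1 ± 10.5 to 906 ± 54.2 FPKM and the chaperone gene Dnajb1 fell from 323 ± 37.2 to 158 ± 10.9 FPKM. Calls were 2 higher and 1 lower without laminin-negative replicate 2, 2 and 3 without laminin-positive replicate 1, 3 and 1 without laminin-positive replicate 2, and 4 and 3 without laminin-negative replicate 1. The counts depended on scaling, with 7 higher and 1 lower under quantile normalization 6 and 1 with equal FPKM sums, and 2 and 2 with trimmed mean scaling or with length and GC trends removed. Without variance shared across genes limma called 0 higher and 0 lower, against 3 and 1 at an unadjusted p under 0.05.

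Markers of Sertoli, germ, endothelial, macrophage and erythroid cells were low in level, apart from Aard and Cdh5. Those that passed the test were higher in laminin-positive cells, apart from Cdh5 and Tek. Smooth muscle and pericyte markers, given above, reached 3603 (Acta2) and 125 FPKM (Mcam) in laminin-positive cells. Macrophage and leukocyte markers were higher in 8 of 8 tested cases, also adjusted over the list alone (median log2 difference 2.12, camera adjusted p = 1.42e-05, and adjusted p = 0.242 with an estimated correlation). Lyz2, the most abundant of them in laminin-positive cells, was at 1.27 ± 0.967 and 11.8 ± 0.205 FPKM, and complement gene C1qc was at 0.327 ± 0.122 and 8.78 ± 0.568 FPKM. The Lyz2 call was lost without variance shared across genes (0.0861). Sertoli cell markers were higher in 7 of 8 cases, or 7 higher and 1 lower adjusted over the list alone (median log2 difference 1.32, camera adjusted p = 7.58e-04, and adjusted p = 0.242 with an estimated correlation). Of the 8, 3 were called higher without variance shared across genes, and Cldn11 was not (0.0535). Cldn11, a tight junction gene, rose from 1.07 ± 0.285 to 16.7 ± 5.28 FPKM and Aard from 50.4 ± 1.95 to 102 ± 3.18 FPKM. Sox9 was at 9.69 ± 0.865 and 7.71 ± 1.55 FPKM (limma adjusted p = 0.0674), and was called lower without laminin-positive replicate 1 (0.00917), with the replicate block (0.0225), under quantile normalization (0.0464) and with length and GC trends removed (0.0198), in a range of 0.00917 to 0.542.

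Germ cell markers were higher in 7 of 8 cases, likewise adjusted over the list alone (median log2 difference 0.92, camera adjusted p = 0.00210), but in only 1 of 8 without variance shared across genes. They had adjusted p = 0.242 with an estimated correlation, and 0.0568 when only genes of at least 5 FPKM were tested, in a range of 0.00105 to 0.0568 over the alternatives with the preset correlation. Their levels were low, with Zbtb16, a gene of undifferentiated spermatogonia, at 2.17 ± 0.346 and 6.66 ± 0.0996 FPKM and Dazl, which was not called without shared variance, at 2.94 ± 0.539 and 6.56 ± 0.364 FPKM. Endothelial markers were higher in 2 of 5 tested cases (Esam and Emcn) and lower in 2 (Cdh5 and Tek), the same adjusted over the list alone. Of them, 1 was called higher and 1 lower without variance shared across genes. Their median log2 difference was 0.10, while the mean was −0.36 and the list test pointed down (camera adjusted p = 0.823). Cdh5, the cadherin of endothelial junctions (chromosome 8, 104101625 to 104144511), fell from 169 ± 5.58 to 9.57 ± 0.453 FPKM, and Esam rose from 0.373 ± 0.223 to 6.39 ± 0.0812 FPKM. Erythroid markers did not exceed 0.819 FPKM in any library.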

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

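The size threshold, equal FPKM sums without Rn45s, the removal of length and GC trends, and the restriction to unshared loci were tests chosen only after the results were seen, and the other alternatives were fixed before. No called direction was reversed among the named genes and the gene lists, but many of these genes were named for large differences in the same data. The 99 results compared also held gene counts and mean correlations, which have no direction to reverse. Without variance shared across genes, 1346 genes were higher and 1211 lower, and with a log2 difference of at least 1 there were 900 and 727. The variance of each gene then rests on 2 residual degrees of freedom alone, and the size threshold takes a part of the calls. Leaving out each replicate in turn gave 2587 to 3254 higher and 2610 to 3064 lower genes, with the lone sample of a population assumed to vary like the other population. Differences between replicates were not shared by the populations (correlation 0.00809 across genes). This cannot show whether equally numbered samples came from the same animals or sort. The replicate block gave 3376 higher and 3343 lower genes.

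With an estimated correlation, which leaves 2 residual degrees of freedom, all 13 called lists lost their call at unchanged medians. These were −2.32 (steroidogenesis), −2.87 (fetal Leydig), −2.35 (adult Leydig), 0.55 (Notch), 3.80 (smooth muscle), 2.04 (pericyte), 0.57 (other basement membrane), 3.23 (laminin receptors), −0.47 (interstitial matrix), −0.91 (cholesterol), 1.32 (Sertoli), 0.92 (germ cell) and 2.12 (macrophage). Under the 14 other alternatives 10 of these lists kept their call, and the 7 uncalled lists stayed uncalled under all 15. Other basement membrane genes lost theirs at a median of 0.57 with no filter (adjusted p = 0.0712), no intensity trend (0.0761) and the replicate block (0.0529), at 0.69 with equal FPKM sums (0.0662) and at 0.47 with length and GC trends removed (0.0825). Leaving out a replicate moved that median between 0.52 and 0.62 and lost the call without laminin-negative replicate 2 (0.0546). Interstitial matrix genes lost theirs under quantile normalization (−0.27, adjusted p = 0.129), and germ cell genes at 5 FPKM or more (1.11, 0.0568), where fewer genes were tested. For the others the cause was not tested. The mean correlation within groups moved to 0.992 with a pseudocount of 0.1, and that between groups to 0.867 with that pseudocount and 0.853 at 5 FPKM or more.

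Of the 69 named genes tested, 47 kept their side of the threshold under each of the 16 alternatives that tested them, and 19 lost their call without shared variance. Alternatives that need counts and the list test without shared variance or on unshared loci were not run. Values well below 1 FPKM rest on few fragments, so differences between such genes are limited by depth.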

Other observations

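The gene lists in the next paragraphs, the genes named in them, the tests of carried-over cells and the endothelial test were chosen only after the results were seen, and the tests of macrophage and Sertoli genes and of overlapping genes were fixed before their values were looked at.

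Of 16 smooth muscle regulators and channels, 14 were higher in laminin-positive cells and 0 lower (median log2 difference 1.21, camera adjusted p = 6.39e-08, and adjusted p = 0.194 with an estimated correlation), or 8 higher without variance shared across genes. The coactivator gene Myocd stood at 1.55 ± 0.389 FPKM in laminin-negative and 38.8 ± 0.329 in laminin-positive cells, the kinase gene Prkg1 at 0.278 ± 0.0692 and 17.6 ± 1.27, and the endothelin receptor gene Ednrb at 0.520 ± 0.207 and 19.8 ± 1.76. Of 15 integrin subunits, 13 were higher and 0 lower (median log2 difference 0.76, camera adjusted p = 3.75e-07, and adjusted p = 0.194 with an estimated correlation), led by Itga8 at 0.659 ± 0.0693 and 33.3 ± 1.32 FPKM. The integrin list shares members with the laminin receptor list.

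Of 10 genes for IGF ligands, receptors and binding proteins, 8 were lower in laminin-positive cells (median log2 difference −0.96, camera adjusted p = 3.33e-06, and adjusted p = 0.194 with an estimated correlation), among them Igfbp2 at 159.6 ± 10.1 and 7.17 ± 0.990 FPKM and Igfbp3 at 42.5 ± 0.316 and 1.59 ± 0.238 FPKM. Of 8 tested complement genes in a list that leaves out C1q, 7 were lower and 1, C7, was higher (median log2 difference −1.02, camera adjusted p = 3.43e-04, and adjusted p = 0.194 with an estimated correlation). Without variance shared across genes 5 of the 10 IGF genes and 4 of the 8 complement genes were called lower. The C7 call was lost by that alternative and without laminin-negative replicate 1 or laminin-positive replicate 2, where limma called 0 complement genes higher, as at an unadjusted p under 0.05. C1qa, C1qb and C1qc, which stand in the macrophage list, were higher in laminin-positive cells, with log2 differences of 2.29, 2.80 and 2.88. Wnt ligands split into 3 higher (Wnt4, Wnt5a and Wnt5b) and 4 lower (Wnt2, Wnt2b, Wnt6 and Wnt9a), with Wnt6 at 188 ± 11.7 and 24.1 ± 0.0934 FPKM and Wnt2b at 26.5 ± 2.96 and 0.506 ± 0.0451 FPKM (camera adjusted p = 0.149 for the list, 0.0375 to 0.417 over the alternatives). Without variance shared across genes 2 were called higher and 3 lower. Cytosolic ribosomal protein genes were lower in 64 of 82 cases by a small amount (median log2 difference −0.37, camera adjusted p = 6.36e-09, and adjusted p = 0.380 with an estimated correlation). With equal FPKM sums 52 were lower, under quantile normalization 39, without laminin-positive replicate 1 42, without laminin-positive replicate 2 41, and without shared variance 11.

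Steroidogenic transcripts were still present in laminin-positive libraries, from Hsd3b6 at 0.938 FPKM to Cyb5a at 64.3 FPKM among the 13 steroidogenesis genes that were lower. These genes kept 3.17% (Lhcgr) to 51.2% (Cyb5a) of their laminin-negative mean. Their median share was 17.6% and 20.02% in the pairs of equally numbered libraries. Carry-over of laminin-negative cells of average make-up would leave every abundant transcript at or above such a share. Among 1474 genes at 50 FPKM or more in both laminin-negative libraries, the lowest share was that of Clec3b, at most 0.359%, which argues against such cells as the source of more than that share. A carried-over steroidogenic subset may still be the source. Genes made only by that subset would keep equal shares. The shares were close for Lhcgr (3.17%), Hsd3b6 (3.23%) and Cyp17a1 (3.40%). They were higher for Cyp11a1 (7.79%), Hsd3b1 (8.18%) and Star (10.8%), a 3.41-fold range over these genes. The data do not show which genes only such a subset makes, so the shares cannot decide this. Expression at a lower level by the laminin-positive cells themselves, the biological reading, is open and untested.

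Macrophage and Sertoli cell markers were higher in laminin-positive libraries although the sort took EGFP-expressing cells only. A second macrophage list gave 9 of 12 genes (75%) with both laminin-positive libraries above both laminin-negative ones, such as Pf4 at 0.483 and 7.69 FPKM and Tyrobp at 0.282 and 4.46 FPKM, while H2-Aa, H2-Ab1 and Cd74 had lower means. This lies between the 80% set for an admixture of macrophages and the 50% set against it, so a small share of macrophages may account for part of the signal. A second Sertoli list gave 6 of 11 genes (54.5%), with 3 called higher (Shbg, Mro and Etd) and 3 lower (Clu, Trf and Nr0b1), and 7 of the 11 were already at 1 FPKM or more in laminin-negative cells, against 3 of the 12 macrophage genes. Clu, abundant in Sertoli cells, was at 133 FPKM in laminin-negative cells, so that its own level there would hide a small share, and an admixture cannot be told apart from expression by the sorted cells.

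Cdh5 was abundant in laminin-negative cells, at 169 ± 5.58 FPKM. Endothelial cells would bring their other abundant transcripts, yet the median of the 9 other endothelial markers was at most 0.307% of Cdh5 in these libraries, and the highest of them, Egfl7, reached 5.23 FPKM, which argues against such cells as the source. In GENCODE M21, 1 other gene overlaps the span of Cdh5 but 0 overlap an exon of it, which argues against reads of an annotated overlapping gene. The annotation used by the submitters is not known, and unannotated transcripts were not covered. Reads from related cadherins were not tested and stay open. Expression of Cdh5 by the laminin-negative interstitial cells is therefore a hypothesis that may be worth testing by staining.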
